A study of Mus musculus with 26 samples.

How the data were processed

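Liver RNA-seq was analysed from 1 deposited table of read counts per gene. Per the submitters' processing notes, reads were handled with fastp 1.3.3, HISAT2 2.2.1, featureCounts and Subread 2.0.2 on the mouse build mm10. Per the file headers, the deposited counts were made with featureCounts 2.1.1 over exons of the GENCODE vM25 annotation in paired mode, with no strand option and no counting of multi-mapping reads. The 2 sources give different versions, and both are stated as found. The options in the header count both mates of a pair, so the counts are of reads. Without strand, reads of a gene and of an antisense partner cannot be told apart, and members of near-identical families such as the major urinary proteins lose shared reads. The counts were not normalized by the authors, per the file headers and the whole-number values.

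The table held 55401 genes, of which 55141 IDs matched a symbol in the gene name table used here; 213 with a shared symbol were kept under their ID. Columns were matched to samples by the library names in the labels. There were 9 untreated HFD and 8 UCMSC-Exos libraries, and 1 per-sample column that matched no sample was not used. The labels' text plans 9 mice per group. The 9 LSCR samples were not analysed here. No label gives a cage, litter, date or sequencing batch, so none could be entered as a term.

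Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by TMM, and a robust quasi-likelihood F test compared UCMSC-Exos with untreated HFD, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.29. CPM values use the effective library size. Log2 CPM used a prior count of 2. The 49 gene lists were fixed before the data were examined, as were the design, the named-gene rule and the first set of alternatives. The 46 lists with 5 or more tested members were tested by camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and by fry. Library measures were compared with exact permutation tests over all 24310 splits. Symbol stems with 5 or more tested genes were tested by Fisher's exact test, 1024 stem and direction pairs in all.

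Named genes are the 12 with the largest rise and the 12 with the largest fall among those passing with a mean of at least 1 CPM (1 unnamed model was passed over), all tested members of the study panel, and in each other list up to 4 members of smallest p that passed, or 2 where none did. Examples in the text come from these; 2 of the named genes are not reported here. The largest falls and rises without untreated HFD 3 and 9 were added after the data were seen.

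Alternatives were RLE and upper quartile scaling, no filter, at least 1 CPM in 8 samples, the replicate number as a block, at most 3 surrogate variables (sva 3.50.0), leaving out each library, the Wald test of DESeq2 1.42.0, and limma voom with quality weights. Leaving out untreated HFD 3 and 9, and halving counts, were added later. The steps were tested on simulated counts for 16004 genes at the real means, library sizes and dispersions. At simulated log2 changes of 0.5, 1 and 2, 52.2%, 82.1% and 97% of 67, 67 and 66 changed genes were recovered, and 8 of 171 calls were false (4.68%). Of the other calls, 154 were these changed genes and 9 were members of a list shifted on purpose. That list, shifted by 0.5, was called and 0 others were. The simulated genes varied independently of each other. The simulation therefore cannot test list calls at the real correlation between genes, estimated at 0.878 for the mitochondrially encoded list. No pair of libraries agreed within the sampling noise of independent reads. The closest pair, UCMSC-Exos 2 and 3, had a median chi-square 3.89 times the value such noise gives. Both mates of a pair are counted, so the real sampling noise is larger and the ratio to it smaller.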

Results

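Liver RNA was sequenced in male C57BL/6 mice that had been kept on a high-fat diet from 4 weeks of age for 18 weeks. The growth text of the labels calls the diet high-fat, and the series design adds high cholesterol. The series holds 26 samples in 3 groups. Untreated mice on the diet (untreated HFD, 9 libraries) were compared with mice given tail-vein injections of exosomes derived from UCMSCs (UCMSC-Exos, 8 libraries) every 72 hours for 8 weeks. No injection is listed for the untreated mice. In every result below, exosomes therefore cannot be told apart from repeated injection, or from a cage or cohort shared by the group. Exosomes are small membrane vesicles released by cells. The third group, LSCR, described as a nanotherapeutic with 2 payloads, has 9 samples that were not analysed here. The series title names steatosis, antioxidant enzymes, M2 polarization of macrophages and recruitment of neutrophils as its subjects, and genes of each are given below. Total counts ran from 32.9 to 36.1 M reads per library, with both mates of a pair counted.

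In livers of the UCMSC-Exos group, genes that are higher in male than in female mouse liver rose strongly, immunoglobulin transcripts rose, and interferon-stimulated genes fell. Mup7, a major urinary protein secreted by hepatocytes, went from 26.9 CPM ± 40.9 (SD, n = 9) to 3327 CPM ± 1982 (SD, n = 8). Igha, the constant region of immunoglobulin A, went from 2.1 ± 0.64 to 45.5 ± 14.2 CPM. Ifit2, an antiviral protein induced by interferon, went from 79.5 ± 11.7 to 23.2 ± 7.76 CPM. Scd1, the desaturase that makes monounsaturated fatty acids, went from 14260 ± 4822 to 4840 ± 1161 CPM. On mm10 these genes span chromosome 4 from 60066469 to 60070475 (Mup7), chromosome 12 from 113254830 to 113260236 (Igha), and chromosome 19 from 34550694 to 34576419 (Ifit2) and from 44394455 to 44407879 (Scd1).

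Of 16238 genes tested with edgeR's quasi-likelihood test, 3274 passed an adjusted p of 0.05, 1580 of them higher and 1694 lower in UCMSC-Exos. At a log2 fold change of at least 1, 252 were higher and 394 lower, 646 in all. The count was 5823 without UCMSC-Exos 9, a library that lay among the untreated ones on the first principal component, 2005 without UCMSC-Exos 3, 2086 without UCMSC-Exos 2, 1007 with 3 surrogate variables in the model, and 7711 with limma voom and quality weights. The count of 646 became 1455, 215 and 1537 without UCMSC-Exos 9, with surrogate variables and with voom. Without untreated HFD 3 and 9, which held transcripts of other tissues and were left out together only after the data were seen, 3341 genes passed, and 2642 of them were among the 3274.

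**Figure D1:**
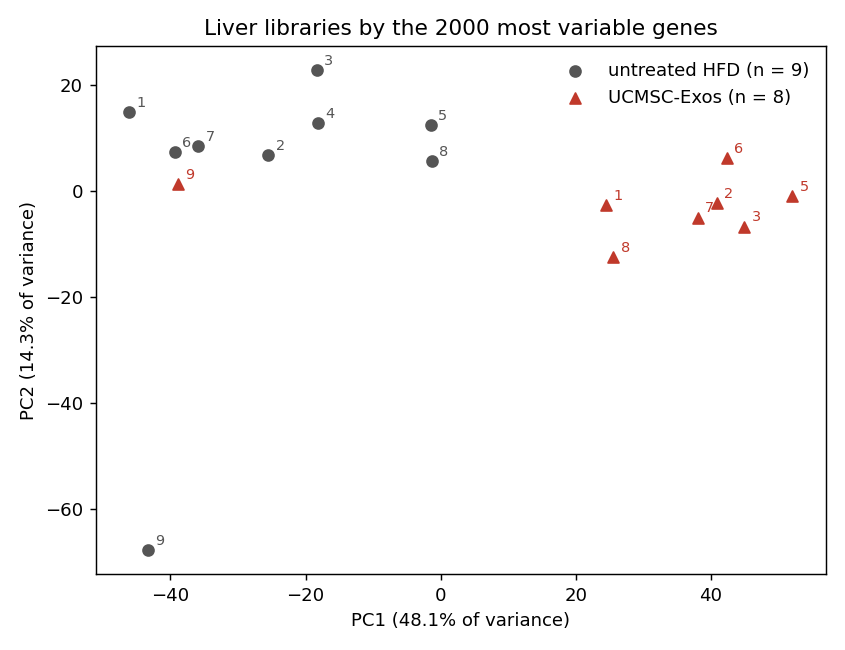
Position of each library on the first 2 principal components of the 2000 most variable genes (log2 CPM), with PC1 holding 48.1% and PC2 14.3% of the variance; numbers are replicate numbers. Of the 8 UCMSC-Exos libraries, 7 lie to the right of all untreated libraries on PC1, UCMSC-Exos 9 lies at −38.9 among the untreated ones, and untreated HFD 9 lies apart at −67.7 on PC2.

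Male-biased genes rose. Of 19 tested members of that list, 17 rose and none fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 1.59. Cyp7b1, an oxysterol hydroxylase, rose by 3.18 ± 0.33 on the log2 scale (SE; edgeR adjusted p = 1.34e-05), with 8 of 8 treated libraries above the untreated median. Hsd3b5, a steroid dehydrogenase of male liver, rose by 7.84 ± 0.86 (edgeR adjusted p = 3.1e-05) from 0.27 ± 0.35 CPM. Cyp2d9 and Elovl3, a cytochrome P450 and a fatty acid elongase, rose by 1.27 ± 0.17 and 2.09 ± 0.27. Camera gave an adjusted p of 1.71e-15 for the list, and adjusted p = 0.257 with an estimated correlation. Of the 12 named genes with the largest rise, 5 were major urinary protein genes: Mup7, Mup11, Mup1, Mup16 and Mup15. Their log2 fold changes were 6.95, 4.96, 4.95, 4.49 and 4.29. These genes lie in a cluster of near-identical copies on chromosome 4, so the share of each copy is uncertain. In UCMSC-Exos 9 the mean log2 CPM of the male-biased list was 0.40 above the untreated mean, against 2.59 in the other treated libraries. Among 10 female-biased genes 3 fell and none rose (3 and 0 adjusted over the list alone). Cyp17a1, Cyp2a4 and Cyp2a22 fell by 1.02, 3.19 and 0.94. Camera gave that list an adjusted p of 0.0233 and adjusted p = 0.463 with an estimated correlation. The list mean was −0.20 from the untreated mean in UCMSC-Exos 9 and −1.07 in the other treated libraries. The list's call was lost without UCMSC-Exos 5 (adjusted p = 0.0531) and with surrogate variables (0.154, at a median of −0.41), and its median was −0.77 without UCMSC-Exos 8 and −0.32 without UCMSC-Exos 5. Surrogate variables also ended the calls of Mup15 at a log2 fold change of 2.14 (adjusted p = 0.0658), Cyp2a4 at −2.74 (0.0612) and Cyp2a22 at −0.67 (0.138).

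Genes of hepatocyte function rose as well. Of 19 genes of bile acid synthesis and sterol export 16 rose and none fell (17 and 0 adjusted over the list alone). Besides Cyp7b1, the organic anion transporter Slco1a1 rose by 3.44 ± 0.54 and Slc10a1, the main bile acid uptake carrier, by 1.11 ± 0.26. Of 19 genes of secreted proteins and hepatocyte identity, 14 rose and none fell (15 and 0 adjusted over the list alone). They included Ahsg, Ttr and the transcription factor Hnf4a, with log2 fold changes of 0.91, 0.66 and 0.67. In the list of the urea cycle and amino acid catabolism 13 of 20 rose and none fell (17 and 0 adjusted over the list alone). Tdo2 rose by 0.99, Hal by 1.5 and Cps1, the entry enzyme of the urea cycle, by 0.89. For these 3 lists camera gave adjusted p of 1.28e-07, 2.06e-08 and 1.0e-07. With an estimated correlation the values were adjusted p = 0.325, 0.325 and 0.452. In UCMSC-Exos 9 the list means lay below the untreated mean, at −0.28, −0.15 and −0.67, against 0.94, 0.61 and 0.81 in the other treated libraries. With surrogate variables the calls were lost for the urea cycle list at a median of 0.04 (adjusted p = 0.297), Slc10a1 at 0.42 (0.135), Hal at 0.40 (0.393), Cps1 at 0.20 (0.45) and Hnf4a at 0.28 (0.0981). Lists that mark library quality were called beside these. The 13 mitochondrially encoded genes had a median log2 fold change of 0.51 with none passing alone (camera adjusted p = 0.00163, adjusted p = 0.522 with an estimated correlation). Their mean stood 0.10 above the untreated mean in UCMSC-Exos 9 and 0.94 in the other treated libraries, and untreated HFD 3 and 9 stood at −3.39 and 1.67 from the other untreated ones. The median was 0.81 without untreated HFD 9 and 0.64 without both, where mt-Atp8 and mt-Nd3 passed (edgeR adjusted p = 0.0183 and 0.0128). Without UCMSC-Exos 9 these 2 genes passed too (0.0432 and 0.018), as did mt-Atp8 without untreated HFD 3 (0.0131) and mt-Nd3 without untreated HFD 9 (0.0104). The 34 cytosolic ribosomal protein genes had a median of 0.10, with 1 rising and none falling (0 and 0 adjusted over the list alone; camera adjusted p = 0.0073, adjusted p = 0.522 with an estimated correlation). That call was lost without UCMSC-Exos 6 (adjusted p = 0.0643).

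Immunoglobulin genes rose in every treated library, UCMSC-Exos 9 included. Of 18 genes of B and plasma cells, 7 rose and none fell (8 and 1 adjusted over the list alone). Igha rose by 4.44 ± 0.24 on the log2 scale (edgeR adjusted p = 3.84e-09), and Jchain, which joins IgA and IgM polymers, by 2.97 ± 0.26 (edgeR adjusted p = 1.24e-06). The light chain gene Igkc and the heavy chain gene Ighg2c rose by 2.67 ± 0.24 and 3.90 ± 0.49. The variable segments Igkv15-103 and Igkv4-50 were close to 0 in untreated livers, at 0.018 and 0.013 CPM, and stood at 3.40 ± 1.17 and 2.25 ± 0.90 CPM in treated ones. Camera gave an adjusted p of 7.71e-07 for the list, and adjusted p = 0.238 with an estimated correlation. Erythroid and haemoglobin transcripts moved with this group: 4 of 8 rose and none fell (6 and 0 adjusted over the list alone), among them Alas2 by 1.06 ± 0.14 and Hba-a1 by 1.31 ± 0.30. Camera gave that list an adjusted p of 5.16e-04 and adjusted p = 0.325 with an estimated correlation. Of 23 T and NK cell genes 6 rose and 1 fell (9 and 2 adjusted over the list alone), with Cd4 at 1.62 ± 0.22 and Cd2 at 1.18 ± 0.22 among those that rose. The T and NK cell list had a camera adjusted p of 0.00329, adjusted p = 0.522 with an estimated correlation, and 0.0662 without UCMSC-Exos 9, where its median went from 0.59 to 0.36. Its mean lay 1.20 above the untreated mean in UCMSC-Exos 9 and 0.19 above it in the other treated libraries. The erythroid list lay 0.16 and 0.92 above it, in the same order.

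**Figure D2:**
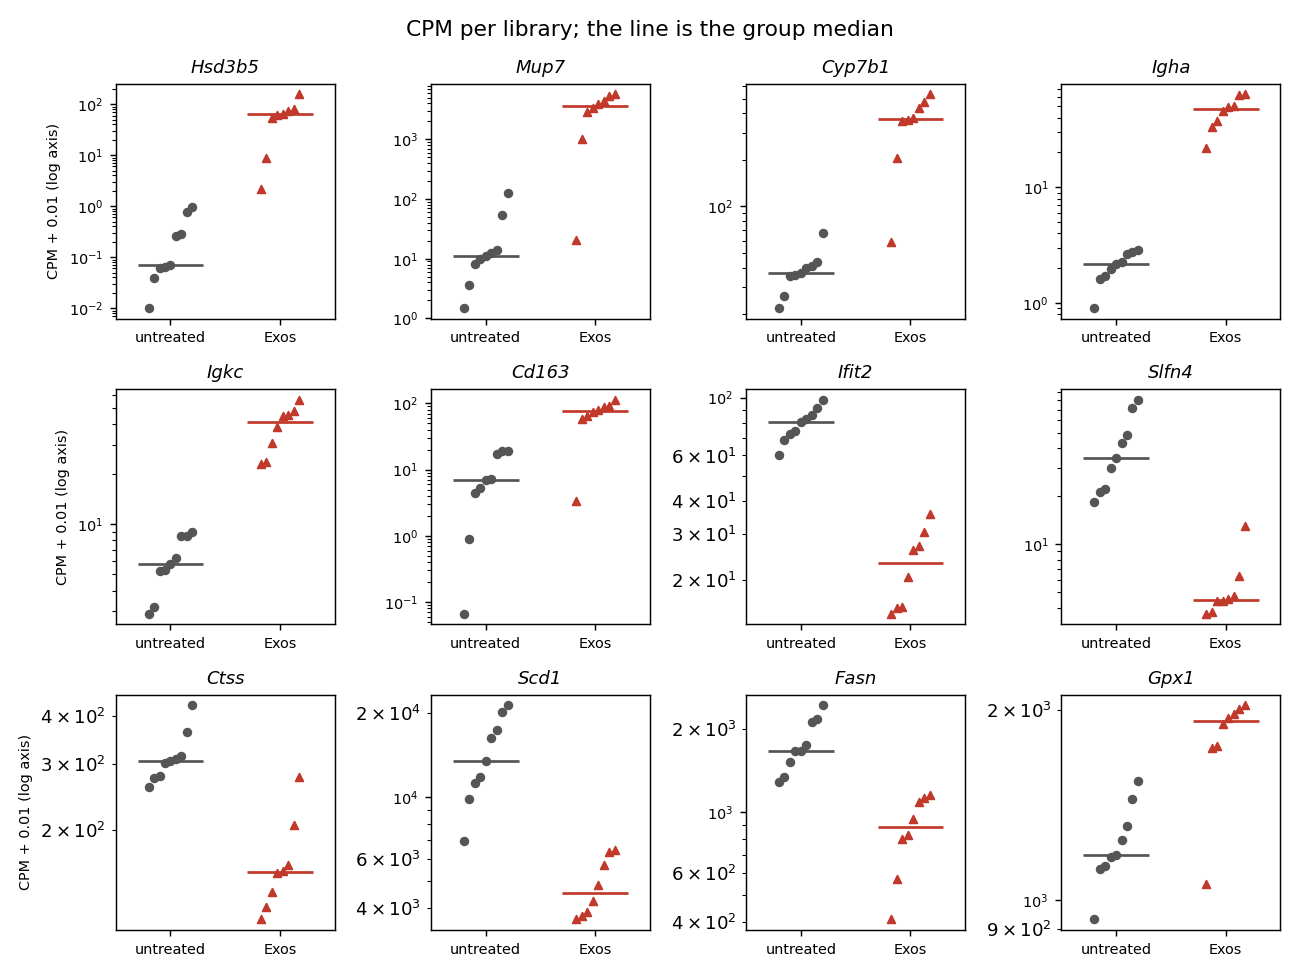
CPM per library, with 0.01 added, on log axes for 12 genes in untreated HFD (circles, n = 9) and UCMSC-Exos (triangles, n = 8); the line is the group median. For Mup7 and Cd163, UCMSC-Exos 9 stands at 20.6 and 3.39 CPM among the untreated libraries, while for Igha all 8 treated libraries lie above all 9 untreated ones.

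Interferon-stimulated genes fell almost without exception: 25 of 27 fell and none rose (26 and 0 adjusted over the list alone), with a median log2 fold change of −1.02. Ifit2, Oasl2, Oas3 and Oas2 changed by −1.77 ± 0.17, −1.70 ± 0.17, −1.78 ± 0.19 and −1.19 ± 0.13, all 4 below the untreated median in 8 of 8 treated libraries. Camera gave an adjusted p of 2.11e-20, and adjusted p = 0.257 with an estimated correlation. By symbol stem, which was looked at after the data were seen, all 8 tested Slfn genes, 7 of 7 Oas and 6 of 6 Ifit genes fell. In other stems a part fell, such as 14 of 18 Ifi, 7 of 11 Gbp, 6 of 12 Parp and 13 of 43 Trim genes. In UCMSC-Exos 9 the mean of the interferon list was −1.26 from the untreated mean, and −1.10 in the other treated libraries.

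Part of the genes of antigen presentation, monocytes and matrix fell too. Of 15 genes of MHC class II and dendritic cells 8 fell and none rose (11 and 0 adjusted over the list alone). The class II transactivator Ciita changed by −0.88 ± 0.17 and H2-Ab1 by −1.01 ± 0.24. Of 20 genes of monocytes and lipid-associated macrophages 5 fell and none rose (7 and 0 adjusted over the list alone), with Ctss at −0.92 ± 0.15, Ly6c2 at −1.06 ± 0.18 and the chemokine receptor Ccr2 at −1.12 ± 0.21. Of 27 genes of stellate cells and fibrosis 8 fell and none rose (16 fell and 1 rose adjusted over the list alone), with Colec11 at −0.60 ± 0.12 and the basement membrane collagen Col4a1 at −0.89 ± 0.19. Of 24 inflammatory cytokines and NF-kB targets 10 fell and none rose (11 and 0 adjusted over the list alone). The chemokines Cxcl16, Ccl3 and Ccl4 changed by −0.88, −1.07 and −1.15. Camera adjusted p for these 4 lists were 8.97e-06, 3.28e-05, 2.84e-05 and 0.00667, and with an estimated correlation adjusted p = 0.325, 0.452, 0.463 and 0.522. In UCMSC-Exos 9 all 4 lists lay above the untreated mean, by 0.14, 0.52, 0.58 and 0.24, against −0.88, −0.90, −0.90 and −0.45 in the other treated libraries. Of 15 cholangiocyte genes, those of bile duct cells, 1 fell and none rose (0 and 0 adjusted over the list alone), with a median of −1.0 (camera adjusted p = 0.00191, adjusted p = 0.522 with an estimated correlation). The mean of that list was 1.16 above the untreated mean in UCMSC-Exos 9 and −1.56 from it in the other treated libraries. With surrogate variables camera's direction for the cholangiocyte list turned, at a median of −0.03 (adjusted p = 0.797), and fry did not call that list (adjusted p = 0.0676). Surrogate variables also ended the calls of the monocyte list at a median of −0.12 (adjusted p = 0.0771), the inflammatory list at −0.14 (0.094), Ccl3 at −0.91 (0.0754) and Ccl4 at −0.66 (0.245). Without UCMSC-Exos 9 the medians of the monocyte and cholangiocyte lists were −0.83 and −1.86, from −0.43 and −1.0.

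**Figure D3:**
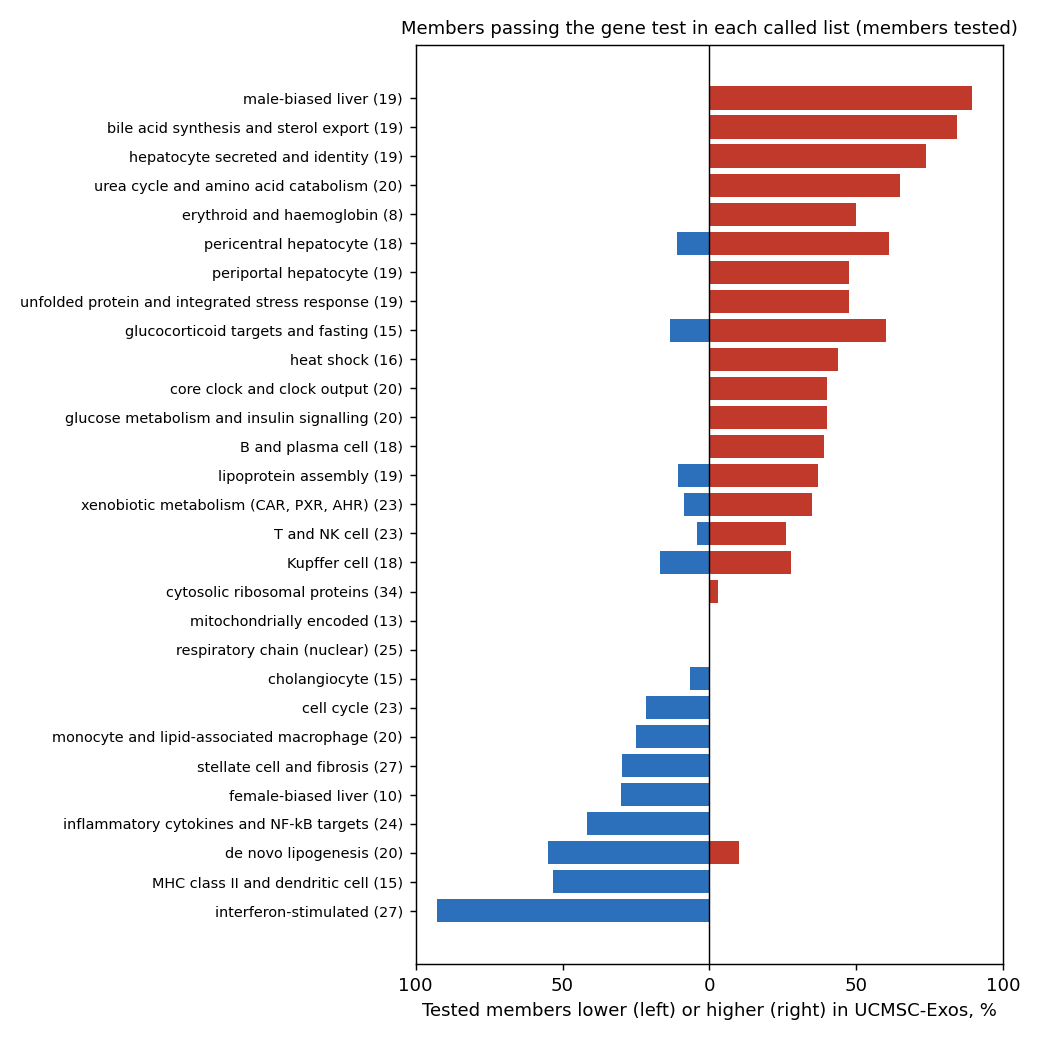
Percent of the tested members of each of the 29 gene lists called by camera (preset correlation) that passed the gene test as lower (left, blue) or higher (right, red) in UCMSC-Exos; the number tested follows each name. No list is called with an estimated correlation, and the interferon-stimulated and male-biased lists have the highest shares.

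For steatosis, lipid-making enzymes fell. Of 20 genes of de novo lipogenesis 11 fell and 2 rose (11 and 3 adjusted over the list alone). Scd1 changed by −1.56 ± 0.21, Fasn, the fatty acid synthase, by −1.04 ± 0.19, and malic enzyme Me1 by −0.70 ± 0.11, while the transcription factor Mlxipl rose by 0.67 ± 0.13. Camera gave an adjusted p of 0.0073, adjusted p = 0.522 with an estimated correlation, and 0.0662 without UCMSC-Exos 9. Among 21 genes of lipid droplets and fatty acid uptake 7 fell and 1 rose (7 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.124). Pparg, G0s2 and the droplet protein Cidec changed by −0.70 ± 0.11, −1.57 ± 0.33 and −1.14 ± 0.27, and the transporter Slc27a2 rose by 0.65 ± 0.13. Of 28 genes of fatty acid oxidation and ketogenesis 2 rose and 2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.301), and of 24 genes of cholesterol synthesis 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.776). With surrogate variables Cidec at −0.83 (adjusted p = 0.125), Mlxipl at 0.38 (0.0774), Slc27a2 at 0.26 (0.0507) and G0s2 at −1.48 (0.103) lost their calls, and the lists of lipid droplets at −0.20 (0.0256) and cholesterol synthesis at −0.14 (0.00748) gained one. The lipid droplet list was also called without UCMSC-Exos 8, at a median of −0.43 (0.0386).

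For the other subjects in the series title, changes went both ways. Of 20 antioxidant enzymes 3 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.255). Gpx1, a glutathione peroxidase, and catalase (Cat) rose by 0.55 ± 0.13 and 0.56 ± 0.16, and Sod3, Gpx3 and Gpx4 changed by −0.44 ± 0.08, −1.36 ± 0.31 and −0.32 ± 0.09. Sod1 and Sod2 did not pass, at 0.15 ± 0.11 and 0.17 ± 0.10. Of 15 genes of M2-type macrophages 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.425), and the median and mean of that list differ in sign, at −0.29 and 0.07. The scavenger receptor Cd163 rose by 3.00 ± 0.71, with 7 of 8 treated libraries above the untreated median, and Ccl24 rose by 1.88 ± 0.36. Il4ra and Msr1 fell, at −0.46 and −0.44 (edgeR adjusted p = 0.0134 and 0.0219). Both lost their calls with surrogate variables, at −0.30 (adjusted p = 0.107) and −0.38 (0.236). Msr1 also lost its call in 2 of the fits that leave out 1 library (highest adjusted p = 0.0507). Mrc1 rose by 0.30 ± 0.11 (edgeR adjusted p = 0.0491) and lost its call in 12 of the 17 fits that leave out 1 library (highest adjusted p = 0.0963). Arg1, which hepatocytes also make, did not pass, at 0.32 ± 0.16. Of 15 genes of M1-type macrophages 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.269), with the Fc receptor Fcgr1 at −1.17 ± 0.16 and Marco at 2.38 ± 0.69. Marco's adjusted p was 0.0501 without UCMSC-Exos 3. Of 17 neutrophil genes 2 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.339). Lcn2, which hepatocytes also make, changed by −1.07 ± 0.29, and Hdc and Mmp8 rose by 0.38 ± 0.12 and 1.06 ± 0.37, losing their calls in 8 and 13 of those 17 fits (highest adjusted p = 0.0695 and 0.137). S100a8 and S100a9 did not pass, at 0.41 ± 0.22 and 0.37 ± 0.26. With surrogate variables Sod3, Gpx3, Gpx4 and Fcgr1 passed, and calls were lost for Cat at 0.01 (adjusted p = 0.943), Gpx1 at 0.15 (0.183), Cd163 at 1.56 (0.108), Ccl24 at 1.04 (0.0606), Mrc1 at 0.18 (0.364) and Marco at 0.57 (0.579). They were also lost for Lcn2 at −1.29 (0.0725), Hdc at 0.48 (0.0593) and Mmp8 at 1.01 (0.238), each with a log2 fold change close to or above the one given. Without UCMSC-Exos 9, Sod2 at 0.23 (0.0315) and Arg1 at 0.44 (0.00279) passed.

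A panel of 34 genes was drawn up from the study's subjects before the data were examined. Of its 31 tested genes 4 rose and 8 fell (4 and 10 adjusted over the list alone). Camera did not call the panel (adjusted p = 0.265), and fry called it as lower (adjusted p = 0.0206). Besides those named above, Acaca, Cd36, Plin2, Ccl2 and Timp1 changed by −0.42, −0.47, −0.45, −0.99 and −1.04. Without 1 library, Plin2 lost its call once (without UCMSC-Exos 3, adjusted p = 0.05), Ccl2 in 8 fits and Timp1 in 11 (highest adjusted p = 0.0689 and 0.0802). Timp1 was at −1.61 without UCMSC-Exos 9. With surrogate variables Acaca at −0.33 (adjusted p = 0.112), Plin2 at −0.26 (0.317), Ccl2 at −0.77 (0.291) and Timp1 at −0.43 (0.147) lost their calls, and the panel as a list was called at a median of −0.15 (0.00837). Not passing were Srebf1 (0.04), Cpt1a (0.25), Ppara (0.25), Nfe2l2 (−0.18), Tnf (−0.28), Il1b (−0.47), Nos2 (0.10), Cd86 (−0.20), Il10 (−0.64), Adgre1 (−0.08), Cxcr2 (−0.39), Col1a1 (−1.29), Acta2 (0.25) and Tgfb1 (−0.29), each as a log2 fold change. Some of these passed without 1 library: without UCMSC-Exos 9, Col1a1 at −1.95 (adjusted p = 2.36e-04), Tgfb1 at −0.39 (0.00124), Cpt1a at 0.29 (0.0313) and Il1b at −0.60 (0.0398). Col1a1 also passed without untreated HFD 5 (0.0398) or 8 (0.0437), Cpt1a without untreated HFD 8 (0.0436), Tgfb1 without untreated HFD 3 (0.0479) or UCMSC-Exos 6 (0.0475), Ppara without UCMSC-Exos 6 (0.0205) and Nfe2l2 without untreated HFD 3 (0.0275). Without untreated HFD 3 and 9 together Tgfb1 (0.0475) and Nfe2l2 (0.0435) passed.

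Each of the 12 named genes with the largest falls was highest in untreated HFD 9 or 3, and Ldb3 still fell without both libraries, by 1.43 (edgeR adjusted p = 0.0375). Of these 12, 11 were highest in untreated HFD 9, among them Tnni2, Fabp3, Ryr1, Cmya5, Nrap, Ldb3, H19, Mylpf, Casq1 and Casq2. That is the library where the 13 genes of the skeletal muscle list summed to 14120 CPM against at most 3.61 in any other library. Ctrl, a pancreatic protease gene, was highest in untreated HFD 3, where the 18 pancreatic acinar genes summed to 16220 CPM against at most 19.1 elsewhere. Tnni2, the largest, had a fitted change of −8.60 ± 2.44 with all libraries and −0.74 (edgeR adjusted p = 0.263) without both. Untreated HFD 3 also had 0.32% of its counts in mitochondrially encoded genes and untreated HFD 9 had 6.67%. Without those 2 libraries, by a choice made after seeing the data, the largest falls included Cyp2a4, Ms4a4c, Slfn4, Sybu and Slfn1 at −3.18, −2.75, −2.73, −2.69 and −2.08. With all libraries and surrogate variables Ldb3 passed and Tnni2 did not, at −1.18 (edgeR adjusted p = 0.248). Nor did Fabp3, Ryr1, Cmya5, Nrap, Ctrl, H19, Mylpf, Casq1 and Casq2, at −1.11 (Nrap) to −0.24 (Casq2) and adjusted p from 0.369 (Ctrl) to 0.856 (Casq2). Cyp2a4 did not pass either (0.0612) but stayed at −2.74, against −3.19 with all libraries and no surrogate variables.

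**Figure D4:**
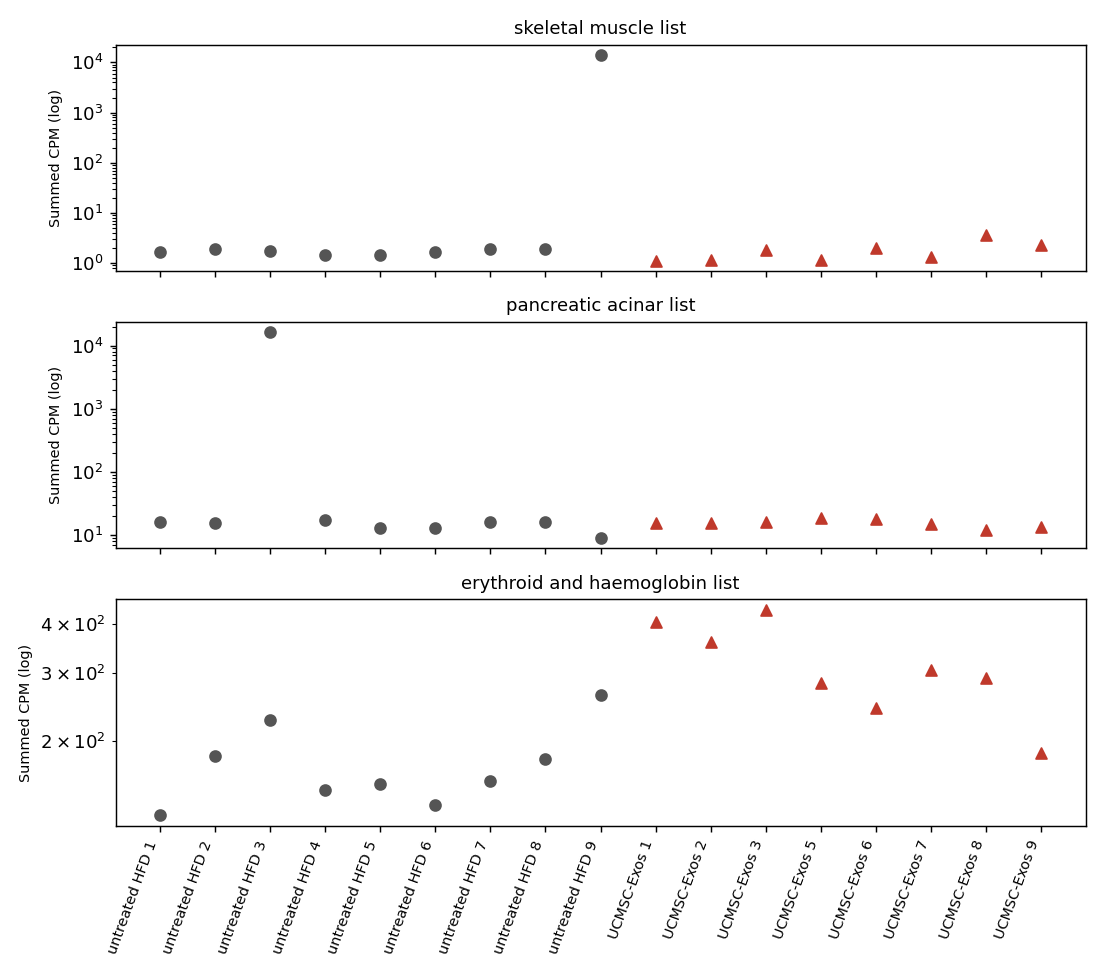
Summed CPM (log axes) of the genes of the skeletal muscle, pancreatic acinar and erythroid lists in each library; circles are untreated HFD and triangles UCMSC-Exos. Muscle genes reach 14120 CPM in untreated HFD 9 and acinar genes 16220 CPM in untreated HFD 3, and erythroid genes run from 187 to 434.5 CPM in treated libraries.

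Treated libraries held 34.1 ± 1.00 M counts and untreated ones 34.8 ± 1.03 M (SD, n = 8 and 9; two-sided exact permutation p = 0.18). The effective size after TMM was lower in UCMSC-Exos, at a difference of −4.41 M (exact permutation p = 0.0168). That followed the TMM factor, with means of 0.943 in UCMSC-Exos and 1.059 in untreated HFD (exact permutation p = 0.01).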

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

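All tests in this part except the counts of splits were chosen after the results they bear on had been seen. For genes, gaps and ranges were taken on log2 CPM, while the values printed below are CPM. A library was taken as far from its group where its gap to the next library, over the group's range, passed Dixon's 95% value. That value gives 1 in 20 for independent normal values and sets no chance rate here. Genes were named in part for their changes in these data, and the genes and lists overlap. Of 524 groups of values 108 passed.

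UCMSC-Exos 9 accounted for 66 of them. It was low within its group, in CPM, for Mup7 (20.6), Mup11 (19.3), Mup1 (1.65), Mup16 (4.96), Capn8 (1.03), Srebf1 (441), Sod1 (384), Sod2 (136), Cat (1846), Gpx1 (1060), Arg1 (526.3), Cd163 (3.39), Ebp (71.8), Cyp7b1 (58.4), Acaa2 (669), Slc27a2 (868), Tdo2 (707), Hal (44.2), Cps1 (1282), Marco (2.00), Timd4 (1.25), Saa4 (260), Serpina3n (408), Fga (1961), Crp (173), Ahsg (3174), Serpina1a (587), Ttr (2084), Etnppl (13.2), Cyp2d9 (672), Cyp1a2 (458), Ces2a (53.4), Nfil3 (15.6), Ciart (6.47), Alas2 (46.7), Adrb3 (4.73), Car3 (757), Snhg11 (4.7) and Mup14 (179). It was high for Col1a1 (440), Timp1 (7.76), Cxcl16 (34.3), H2-Aa (325), Col4a1 (222), Dcn (446), Junb (83.3), Egr1 (71), Ccnd1 (133) and Vil1 (3.29). Its mean log2 CPM was low for the lists bile acid synthesis and sterol export (6.94), lipoprotein assembly (8.13), urea cycle and amino acid catabolism (7.3), respiratory chain (nuclear) (6.84), mitochondrially encoded (7.96), antioxidant enzymes (7), Kupffer cell (5.11), hepatocyte secreted and identity (9.6), pericentral hepatocyte (7.1) and periportal hepatocyte (7.66), and high for MHC class II and dendritic cell (4.35), stellate cell and fibrosis (6.07), cholangiocyte (3.86) and immediate early (4.72). Its TMM factor was 1.18, it had counts in 23189 genes, and its PC1 position was −38.9.

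Untreated HFD 9 was apart for 15 values. It was high in CPM for Tnni2 (695), Fabp3 (538), Ryr1 (725), Cmya5 (454), Nrap (345), Ldb3 (259), H19 (574), Mylpf (417), Casq1 (117), Casq2 (75.5), Cd36 (507) and Rbm24 (34.4). It was high in mean log2 CPM of the lists respiratory chain (nuclear) (7.62), skeletal muscle (9.07) and nuclear long RNA (RNA quality) (5.1).

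Untreated HFD 3 was apart for 16 values. It was high in CPM for Ctrl (314), Pmaip1 (13.3), Axl (296) and BC147527 (8.00). It was low in CPM for Nfe2l2 (59), Slc10a1 (43.6), Scarb1 (121), Lipc (46), mt-Atp8 (0.087), Herpud1 (210), Hspa8 (835), Cd4 (0.58) and Cyp2e1 (1502). It was high in mean log2 CPM of the lists pancreatic acinar (9.04). It was low in mean log2 CPM of the lists mitochondrially encoded (4.85) and core clock and clock output (4.48).

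The other libraries stood apart for 1 to 3 values each: Igkv4-50 in untreated HFD 1 (0.113, high), Igha in untreated HFD 7 (0.896, low), Ldb3 in UCMSC-Exos 3 (0, low), Saa4 in untreated HFD 5 (602, high), Ccnd1 in untreated HFD 8 (87.6, low), Rpl7a in UCMSC-Exos 6 (277, high), Snhg11 in untreated HFD 1 (4.02, low), Slfn4 in UCMSC-Exos 6 (13, high), the list fatty acid oxidation and ketogenesis in UCMSC-Exos 5 (6.98, low), the list cytosolic ribosomal proteins in UCMSC-Exos 6 (7.82, high), the list nuclear long RNA (RNA quality) in UCMSC-Exos 8 (4.91, high), in CPM for genes and mean log2 CPM for lists.

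The largest falls among named genes rest on untreated HFD 9 for 11 of the 12 genes and on untreated HFD 3 for 1. All 13 skeletal muscle genes were over 10 times higher in untreated HFD 9 than in any other library, and all 18 acinar genes in untreated HFD 3. A difference between the groups among the other libraries is argued against for the 12 genes as a set. In fits with no low-count filter their median log2 fold change was −0.20 without both libraries and −6.73 with them. The spread of the former was 0.15, the SD over genes divided by the square root of their number. It takes the genes as independent, which they are not. The 2 libraries left out were those where these genes were highest, so a weaker fall was likely from the start. In the fit without both, 1 gene, Ldb3, still passed at −1.43 (edgeR adjusted p = 0.0479). Muscle and pancreatic tissue taken with these livers may account for most of the pattern, as a hypothesis from the same data. No biological explanation was tested.

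UCMSC-Exos 9 lay with untreated livers on PC1. At 11.8% of separating genes it was nearer the treated mean, within the 2.94 to 40.4% of held-out untreated libraries and under the 75.6 to 95.7% of treated ones, but its interferon-stimulated genes stood at 0.90 of the way to the treated mean (highest untreated 0.19, SD 0.13), which argues against an untreated liver under a wrong label. A uniformly weaker shift was not excluded by interferon minus male-biased positions (0.78; held-out mean 0.01, SD 0.42), and is argued against by interferon-stimulated minus all separating genes (1.17; mean 0.06, SD 0.40). The latter test of each pair was chosen after the first was seen. A swap with an LSCR liver stays open, since that group was not analysed here, and no biological explanation was tested.

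Immunoglobulin transcripts were higher in UCMSC-Exos, with a median log2 fold change of 2.67 over 17 genes that passed. Only genes that rose were taken, which raises that median. More B cells at an unchanged immunoglobulin content is argued against, since B-cell surface genes had a median of 0.42 (median of the single-gene SEs 0.25). More blood in the tissue as the only cause is argued against by the erythroid list, which rose less, at a median of 0.93 (median of the single-gene SEs 0.27). Its haemoglobin genes ran from 0.91 (Hbb-bs) to 1.31 (Hba-a1), and Bpgm and Tfrc stood at 0.09. Since the haemoglobin genes did rise, more blood as a part of the cause stays open. For Igha all 8 treated libraries lay above every untreated one, and the treatment cannot be told apart from housing or a cohort shared by the group, since no label gives a cage or cohort.

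Of 100 splits of the 17 libraries into 9 and 8, 1, the real one, called as many as 3274 genes (highest other 3157). At a log2 fold change of at least 1, 2 called as many as 646 (highest other 729). Chance is unlikely for both counts but not excluded, since only these 100 splits were drawn. The split with 3157 and 729 genes had 6 of the 8 treated libraries in 1 group. For the number of gene lists the real split stood out less, and chance stays open: 5 splits called at least 29, the highest other called 32, and the median of the other splits was 17.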

How the results depend on the processing

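Leaving out untreated HFD 3 and 9 and halving counts were chosen after the results were seen, and the other alternatives before. The 3274 genes became 3259 with RLE, 3106 with upper quartile scaling, 2279 with no filter, 3209 with the CPM filter, 3253 with halved counts, 3341 without untreated HFD 3 and 9 and 4037 with DESeq2. They became 1007 with surrogate variables (786 shared) and 7711 with voom (3227 shared), and ranged from 2005 to 5823 without 1 library, 2005 without UCMSC-Exos 3, 2086 without UCMSC-Exos 2 and 5823 without UCMSC-Exos 9. The 646 genes became 215 with surrogate variables and 1537 with voom, and ranged from 447 to 1455 without 1 library. The 29 gene lists became 0 with an estimated correlation and 23 with fry (21 of the 29, with efferocytosis and the study panel gained). With surrogate variables 23 lists were called, and 17 of the 29 were kept. Calls lost with the direction kept were 10: lipoprotein, urea cycle, heat shock, inflammatory, Kupffer, monocyte, periportal, female-biased, xenobiotic and cell cycle. Another 2, respiratory chain and cholangiocyte, turned and lost their calls too (camera adjusted p = 0.872 and 0.797). The rest of the 23 were not called in the main fit, among them cholesterol synthesis, lipid droplet, NRF2 targets and the study panel. Replicate numbers share no stated meaning, and correlations of same-numbered libraries ran from −0.223 to 0.168; with the replicate block 3027 genes passed and Nos2 was −0.051. The difference in total counts was −0.69 M (exact permutation p = 0.18), and that in effective size after TMM was −4.41 M (exact permutation p = 0.0168). Of 182 named genes that passed, 145 passed without any 1 library and 87 with surrogate variables, which turned Srebf1 (−0.24), Sod1 (−0.10), Sod2 (−0.079), Arg1 (−0.22), S100a9 (−0.15), Pf4 (0.34) and Vil1 (0.16), and camera's direction for lists, here with their medians: respiratory chain (−0.02), antioxidant enzymes (−0.05), neutrophil (−0.15), acute phase (−0.30), sinusoidal endothelial (−0.04), cholangiocyte (−0.03, from −1.0) and immediate early (0.28). Without a filter the adipose list was −0.57. Nrap and Mylpf were 0.34 and 0.35 without untreated HFD 3 and 9, where Srebf1 was 0 and the immediate early list 0.09; they were 0.26 and 0.29 with DESeq2, and Nrap 0.14 and Nos2 −0.077 with voom. Without 1 library Nrap ranged from −6.97 to 0.28, Mylpf from −5.95 to 0.29, Srebf1 from −0.009 to 0.10, Nos2 from −0.079 to 0.23 and Acta2 from −0.13 to 0.72, and the lists cholesterol synthesis from −0.11 to 0.01, immediate early from −0.29 to 0.07 and platelet from −0.11 to 0.15. Fewer samples or another sample set made the leave-out changes, and otherwise the cause was not tested.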

Other observations

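Lists of stress, of glucocorticoid targets and fasting, and of proliferation moved as well. Of 19 genes of the unfolded protein and integrated stress response 9 rose and none fell (13 and 0 adjusted over the list alone). Camera gave that list an adjusted p of 2.05e-07, and adjusted p = 0.257 with an estimated correlation. Among its rising genes were Herpud1 at 1.12 ± 0.14 and Dnajb9 at 0.97 ± 0.16 on the log2 scale. Of 16 heat shock genes 7 rose and none fell (8 and 0 adjusted over the list alone; camera adjusted p = 2.01e-04, adjusted p = 0.463 with an estimated correlation), led by Hspa1b at 1.61 ± 0.34; the list mean was −0.13 from the untreated mean in UCMSC-Exos 9 and 0.45 above it in the other treated libraries. Of 15 genes in the joint list of glucocorticoid targets and fasting 9 rose and 2 fell (10 and 2 adjusted over the list alone). Camera gave that list an adjusted p of 4.03e-04, and adjusted p = 0.257 with an estimated correlation. Tsc22d3 stood at 0.80 ± 0.11, the gluconeogenic enzyme Pck1 at 0.99 ± 0.15 and Fkbp5 at 0.82 ± 0.15. Of 23 cell cycle genes 5 fell and none rose (7 and 0 adjusted over the list alone; camera adjusted p = 5.13e-04, adjusted p = 0.522 with an estimated correlation), with Ccnd1 at −0.98 ± 0.18 and Mcm3 at −0.73 ± 0.17; the list mean was 0.60 above the untreated mean in UCMSC-Exos 9 and −0.60 from it in the other treated libraries. Of 20 clock genes 8 rose and none fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00109, adjusted p = 0.325 with an estimated correlation), led by Nfil3 at 0.95 ± 0.14; the list mean was 0.04 above the untreated mean in UCMSC-Exos 9 and 0.25 in the other treated libraries. The cell cycle list's median was −0.54 without UCMSC-Exos 9, from −0.30. With surrogate variables the calls were lost for the heat shock list at a median of 0.09 (adjusted p = 0.141), the cell cycle list at 0.05 (0.789), Dnajb9 at 0.59 (0.0694), Hspa1b at 0.77 (0.371) and Mcm3 at −0.48 (0.167).

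Of 25 NRF2 targets 2 rose and 7 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.0594). The list was called in 8 of the 17 fits without 1 library, with the smallest adjusted p without untreated HFD 1 (0.0197), without untreated HFD 3 and 9 together (0.0201), and with surrogate variables (5.63e-05). Examples are Gstm3 and Gsta1 both at −1.14 and Osgin1 at 0.87. Kupffer cell genes split, 5 of 18 rising and 3 falling (5 and 3 adjusted over the list alone; camera adjusted p = 0.048, up to 0.153 and not called in 7 of the fits without 1 library, adjusted p = 0.596 with an estimated correlation): the complement genes C1qa and C1qb changed by −0.52 and −0.42, and Hpgd by 0.59. Timd4, a receptor of resident Kupffer cells, rose by 2.39 ± 0.58 and stood at 1.25 CPM in UCMSC-Exos 9. Of 18 pericentral genes 11 rose and 2 fell (13 and 2 adjusted over the list alone), with Cyp2e1 at 1.05 and the Wnt target Axin2 at −0.59, and of 19 periportal genes 9 rose and none fell (10 and 0 adjusted over the list alone). Camera adjusted p were 9.32e-05 and 2.84e-05, and adjusted p = 0.452 for both with an estimated correlation. In UCMSC-Exos 9 the Kupffer, pericentral and periportal list means were −0.48, −0.28 and −0.46 from the untreated mean, against 0.86, 0.67 and 0.68 in the other treated libraries. With surrogate variables the calls were lost for the Kupffer list at a median of −0.04 (adjusted p = 0.891), the periportal list at 0.02 (0.59), Osgin1 at 0.64 (0.0846), Hpgd at 0.21 (0.168), C1qb at −0.32 (0.0922) and Timd4 at 0.73 (0.445).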
